A study of Bos taurus with 4 samples.

How the data were processed

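Early blastocysts of Holstein cattle were collected at 168 h after fertilization in vitro from oocytes of heifers at 8 and at 14 months of age, and were pooled for RNA extraction, per the labels. The heifers received 6 injections of 30 mg FSH, 12 h apart, with ovum pickup 43 h after the last, per the labels. The labels' protocols give linear amplification in 2 rounds of 6 h each and labelling of the amplified RNA with Cy3 or Cy5. Each of the 4 arrays held both ages of 1 heifer, so the pairing by animal lies within the array. In heifers 1 and 2 the 8-month embryos were in Cy5 and the 14-month embryos in Cy3. In heifers 3 and 4 the dyes were the other way round. The heifers were separate animals, and the number of arrays limits the precision. The names of the deposited tables put the 4 arrays on 1 slide, so no slide batch could be tested. Collections at 11 months and RT-qPCR of candidate genes are part of the study per the labels and were not analysed here.

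The scanner tables hold the foreground and local background intensity of each spot at both wavelengths, on a linear scale and not normalized, per the file headers. The image analysis software is not given in the sources used here. A second table, made by the authors, holds a normalized log2 ratio per spot for each heifer. Its direction and scale were found by setting each column against the scanner ratios of the same array. It reads Cy5 over Cy3 on all 4 arrays (r = 0.999, 0.994, 0.943 and 0.915 across bright probes, slopes 1, 1.01, 0.885 and 0.862), which is why its log base was taken as 2. The column medians were 0.0036, 0.00028, 0.0014 and -0.0094. The series value table deposited by the authors holds the same log2 ratios with the sign turned for heifers 3 and 4, so all its columns read 8 over 14 months, with medians of 0.0036, 0.00028, -0.0014 and 0.0094. How the authors corrected background, normalized and centred these ratios is not given in the sources used here, so both tables served as alternatives only.

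Median foreground and background intensities were used. Summary lines at the end of each table, 14 per array, and 1426 control or unnamed spots were left out of the tests, which left 43794 probes. Background was corrected with normexp (offset 50) and log2 ratios were normalized within each array by loess, in which control spots had no weight (limma 3.58.1, R 4.3.3). A channel was above background where its median foreground exceeded the mean of the 153 negative control spots of that array and channel by 2 SD. Probes above background in at least 3 of the 4 samples of at least 1 age were tested, 17685 in all. Of all probes, 21790 had 1 gene symbol in the platform annotation, 0 had several and 22004 had none. The symbols were brought up to date through the synonyms of the RefSeq gene table of assembly ARS-UCD2.0, used for names only: 20025 were current, 1524 were replaced through a synonym and 241 were kept as given. No genome build is given for the probes, so positions in the genome are not reported. Each of 8398 genes was represented by its detected probe with the highest mean intensity.

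The age effect was fitted with lmFit and eBayes on the log2 ratios, with a coefficient of 1 where the 8-month embryos were in Cy5 and -1 where they were in Cy3, and a dye term common to all arrays. The coefficient is log2 of 8 over 14 months. The fit leaves 2 residual degrees of freedom, and its standard error rests on the spread between heifers of the same dye orientation. Tests were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05, and no threshold on the fold was set beyond a separate count of probes with an unadjusted p under 0.05 and at least 1.5-fold difference. A gene above background in none of the 4 samples of one age is given as a background bound, from channel intensities after loess and Aquantile scaling. In it the dim age takes the lowest signal of probes above background on its array, or the probe's own signal where that is higher. The bound allows for the background and not for the spread between heifers. The adjusted p beside it is that of the fitted ratio.

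Before the data were examined, 29 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists with at least 5 detected members (27) were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative, and with fry. The lists covered the inner cell mass and pluripotency, trophectoderm, trophoblast secretory products, primitive endoderm, blastocoel formation, signalling, metabolism, protein synthesis, stress, proliferation, chromatin, imprinting, interferon response and possible other sources of RNA. The rule for named genes took, per direction, up to 12 genes with the largest log2 ratio among those that passed and had the same sign in all 4 heifers, then the 2 members of each list with the smallest p and every member that passed, and a fixed set of marker genes. GATA6 and IFNT2 had no probe under those names, and PPARG was not above background.

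The procedure was tested on simulated data made with the noise and dye terms of the 17685 probes, in which 200 probes were changed in each of 20 draws. With each probe's own moderated variance, 59.2% of probes changed by 0.5 on the log2 scale and 99.8% of those changed by 1 were called, and 9.01% of all calls were false. With variances drawn from the fitted prior, the shares were 6.7%, 88.8% and 4.69%. At an unadjusted p under 0.05, camera found 100% of simulated lists of 30 probes shifted by 0.4, and 5% of unshifted ones. In all draws the noise was independent between arrays and between probes. The shares of false calls therefore do not cover a component shared by the heifers of one dye orientation. Nor do the shares of lists found cover correlated genes.

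Alternatives changed 1 choice at a time: no dye term, no background correction, plain subtraction, an offset of 16, median centring in place of loess, Aquantile scaling after loess, no filter on dim probes or one that needs all 8 samples above background, either of the deposited ratio tables, trended and robust moderation, no moderation, each heifer left out, the mean of a gene's probes, fry in place of camera and an estimated correlation. Mean pixel intensities, negative controls as the background, each dye orientation alone and families of genes with a shared symbol stem were added after the data were seen. Figures were drawn with matplotlib 3.10.9.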

Results

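Gene expression was measured in blastocysts, embryos that have formed a fluid cavity, an outer trophectoderm and an inner cell mass. The embryos were produced in vitro from oocytes collected from the same Holstein heifers at 8 and at 14 months of age, around puberty, with semen of 1 bull. Each of 4 heifers (n = 4) contributed 1 array. On it, pooled early blastocysts from the collection at 8 months were hybridised against those from the collection at 14 months, so that each animal was its own control. In every heifer the collection at 8 months came first, so donor age cannot be told apart from the order or date of the collections. Of the 43794 probes, 43.3% to 51.1% were above background in the 4 samples in Cy3 and 26.9% to 41% in the 4 samples in Cy5. In all, 17685 probes and, with 1 probe each, 8398 named genes were compared. Values are log2 ratios of 8 over 14 months with the standard error of the fit over 4 heifers. This error leaves out the difference between heifers 1 and 2 and heifers 3 and 4, which the dye term takes up. It can therefore be far smaller than the spread over the 4 heifers. For LOC100297725 it was 0.096 where the SD of the 4 heifers was 0.716, and for DAB2 0.098 where the SD was 0.07. Positive values are higher in embryos from the collection at 8 months.

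The first comparison asked which transcripts differed in embryos with the age of the oocyte donor. RALY, an RNA-binding protein of the hnRNP family (probe EMBV3_26019), was 2.06-fold higher at 8 months (log2 1.04 ± 0.21, adjusted p = 0.0379 over genes, not passing over all probes). PRPF6, a splicing factor of the spliceosome's small nuclear RNPs (probe EMBV3_24794), was 1.91-fold higher at 8 months (0.94 ± 0.12, adjusted p = 0.0313). SPC24, part of the kinetochore's NDC80 complex, rose by 0.90 ± 0.10. CXCL14, a chemokine (probe EMBV3_08113), was lower at 8 months (-0.94 ± 0.15, adjusted p = 0.0313). Its signal was above background in 1 of 4 samples at 8 months and 4 of 4 at 14 months, so the size of its fold is uncertain. COL12A1, a fibril-associated collagen (probe EMBV3_19796), was 1.92-fold lower (-0.94 ± 0.15, adjusted p = 0.0313), followed by the histone methyltransferase KMT5B (-0.90 ± 0.10).

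Across all genes, 378 of 8398 passed (limma, adjusted p under 0.05), 143 higher and 235 lower at 8 months. The differences were small: the median size among the 378 was 0.56 on the log2 scale, and the greatest fold was 2.06. In 349 of the 378 the ratio had the same sign in all 4 heifers, which the test itself favours. Over all 8398 genes this share was 27.6%, where independent pairs of heifers would give 23.1%. Further genes with large increases at 8 months were PACSIN3, an adaptor of endocytosis (0.88 ± 0.13), PRKRIP1 (0.87 ± 0.15), the ubiquitin-like membrane protein TMUB1 (0.86 ± 0.17), the tetraspanin TSPAN17 (0.85 ± 0.13) and MPDU1, which acts in the use of dolichol-linked sugars for glycosylation (0.82 ± 0.15, with 1.45 in heifer 3 and 0.56 to 0.67 in the others). PGRMC2 of the membrane-associated progesterone receptor family (0.81 ± 0.12), TMEM161A (0.80 ± 0.14), the DNA-binding protein ARID3A (0.78 ± 0.11) and BoLA-DRB3, a class II histocompatibility beta chain (0.78 ± 0.12), completed the 12 largest increases with the same sign in all 4 heifers. Another detected probe of TMEM161A and of ARID3A had the opposite sign.

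Among the genes lower at 8 months, the cytoplasmic poly(A)-binding protein PABPC1 (-0.85 ± 0.12) and PATL1, an mRNA decay factor (-0.72 ± 0.10), act on mRNA, and NCOA1 is a coactivator of nuclear receptors (-0.77 ± 0.11). The endocytic adaptor DAB2 fell by nearly the same amount in every heifer (-0.87, -0.74, -0.89 and -0.79 in heifers 1 to 4), and all 4 of its detected probes had this sign. The glutamate receptor gene GRM8 was above background in 0 of 4 samples at 8 months and 4 of 4 at 14 months. Its background bound was 1.66-fold lower expression at 8 months (adjusted p = 0.0379). CDC42BPA, a kinase that binds CDC42 (-0.75 ± 0.15, above background in 1 of 4 samples at 8 months, so of uncertain size), the sterol reductase TM7SF2 (-0.72 ± 0.11) and the uncharacterised loci LOC100297725 (-0.79 ± 0.10) and LOC614643 (-0.75 ± 0.11) were also lower. Of 3 detected probes of KMT5B and of NCOA1, 2 had the sign given.

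**Figure D1:**
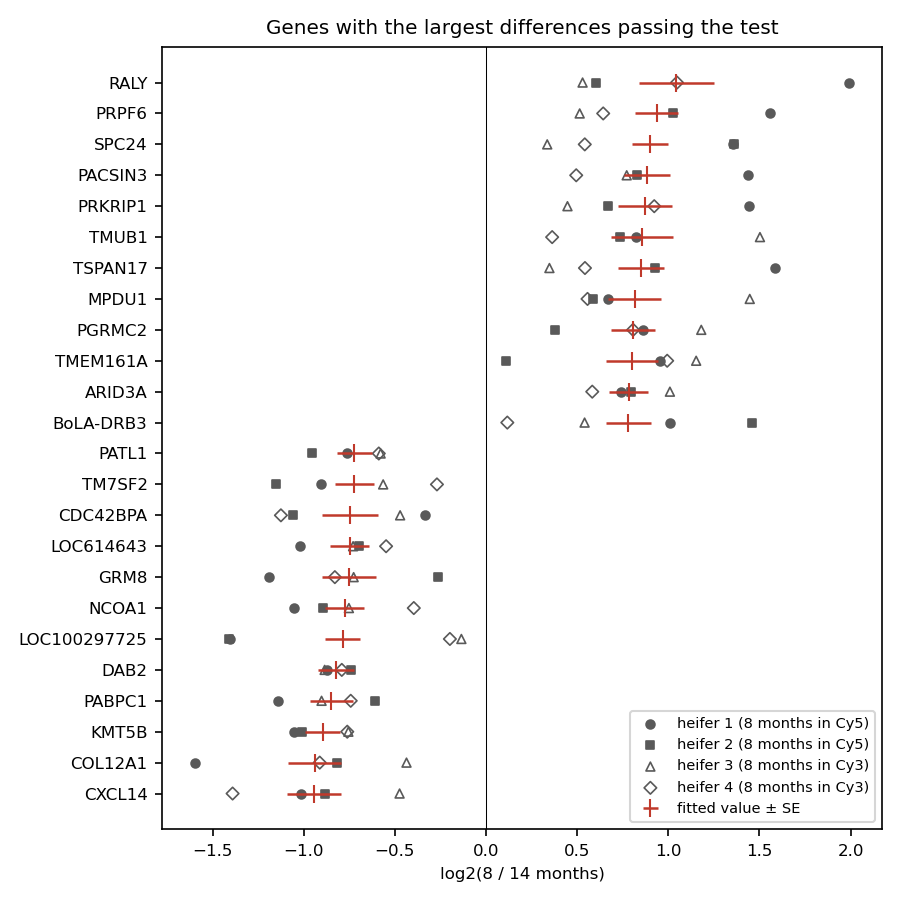
The log2 ratio of 8 over 14 months (x axis) is plotted for each of 4 heifers (points) and as the fitted value with its standard error (red) for the 12 genes per direction with the largest differences that passed and had the same sign in all heifers (y axis). RALY lies at 1.99 in heifer 1 and at 0.53 in heifer 3, whereas the 4 values of DAB2 lie between -0.89 and -0.74.

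At the level of probes, including those with no gene name, 332 of 17685 passed, 98 higher and 234 lower at 8 months, and 157 of them had a gene name. All 332 lay just under the threshold, as the smallest adjusted p was 0.0449 (limma). Of the 378 genes that passed among genes, the probe given passed among all probes for 133 and did not for 245, with an adjusted p of up to 0.0702. No probe of RALY, TMUB1, MPDU1, CDC42BPA or GRM8 passed there, nor, among the list members named as passing, of MVD, MSMO1, HSPA1A, DNAJB1, FADS2, IFI35, NDUFB10, NDUFA4, F11R, RPS2, RPS7, MCM5 or SLC7A5. An unadjusted p under 0.05 with at least 1.5-fold difference was reached by 486 probes (193 higher, 293 lower) and 187 genes (96 higher, 91 lower). An unadjusted p under 0.05 alone was reached by 4682 probes, where chance in independent tests gives 884. The dye term of the same fit reached 3358. The error leaves out the difference between the pairs of heifers, so an excess over 884 can arise without an age effect.

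The values were also set out by dye orientation. Over the tested probes, the ratios correlated at r = 0.61 between heifers 1 and 2 and at r = 0.39 between heifers 3 and 4. Between heifers of opposite orientation, r was 0.0015 to 0.12. What the ratios shared thus lay mostly within a dye orientation, and the fitted error leaves out the difference between the pairs. Across genes, which are not independent replicates, the mean ratio of heifers 1 and 2 correlated with that of heifers 3 and 4 at r = 0.14, and 55.8% of genes had the same sign in both pairs. Of the 378 genes that passed, 368 did. The exceptions included the inducible chaperone HSPA1A (0.13, -0.74, 1.59 and 1.84 in heifers 1 to 4), its co-chaperone DNAJB1 (-0.05, -0.05, 1.04 and 1.00) and the fatty acid desaturase FADS2 (0.84, 1.47, -0.04 and -0.13), for which the increase at 8 months came from one orientation.

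**Figure D2:**
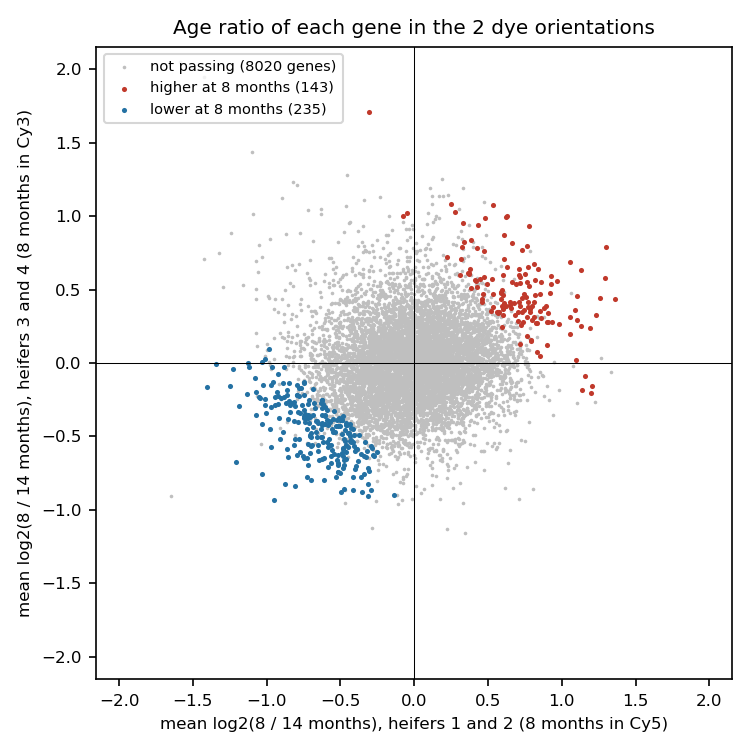
Each point is 1 of 8398 genes, with its mean log2 ratio of 8 over 14 months in heifers 1 and 2 (x axis, 8 months in Cy5) and in heifers 3 and 4 (y axis, 8 months in Cy3). The genes that passed, 143 higher (red) and 235 lower (blue) at 8 months, lie mostly in the quadrants of equal sign, while all genes together form a nearly round cloud (r = 0.14).

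With limma, 0 genes passed without the dye term, without moderation or with mean in place of median pixel intensities, a setting chosen after the data were seen (1544, 1263 and 2252 at an unadjusted p under 0.05), and 0 probes passed in these settings or with plain or no background subtraction (3153, 2785, 4582, 4576 and 4506). Without heifer 1, 2, 3 or 4 there were 0, 0, 2 and 339 genes (1351, 1754, 1719 and 2117 at an unadjusted p under 0.05), and median centring in place of loess, which moved the median of all detected probes to -0.14, gave 2078 genes, 39 higher and 2039 lower.

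The second comparison followed groups of genes fixed in advance, among them the lineages of the blastocyst. Of 18 detected trophectoderm genes, the transcription factors GATA2 (0.61 ± 0.10), TFEB (0.60 ± 0.10) and TEAD4 (0.56 ± 0.10) rose at 8 months, DAB2 fell (-0.82 ± 0.10) and 14 did not pass. Adjusted over the list alone, the counts were also 3 higher and 1 lower. Under median centring the 3 increases no longer passed, and the median of the list went from 0.11 to -0.24. The keratins of this epithelium had ratios of -0.30 ± 0.11 (KRT8, adjusted p = 0.134, saturated in 2 channels) and 0.17 ± 0.11 (KRT18, adjusted p = 0.314), CDX2 had 0.16 ± 0.12 and GATA3 -0.08 ± 0.10. The ratio of CDX2 is of uncertain size, since it was above background in 3 of 4 samples at 8 months and 2 of 4 at 14 months. Of the 16 detected genes of the inner cell mass and pluripotency 0 passed, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. POU5F1 had 0.20 ± 0.11 (adjusted p = 0.285), NANOG 0.09 ± 0.15 (adjusted p = 0.747) and SOX2 0.05 ± 0.12 (adjusted p = 0.815). The sign differed between dye orientations for NANOG (0.27, 0.99, -0.13 and -0.787 in heifers 1 to 4) and POU5F1 (-0.179, -0.121, 0.794 and 0.301). It also differed for KRT18 (0.565, 0.788, -0.199 and -0.468). Their fitted errors leave this out, so fitted values near 0 are not precise for these genes. The ratios of KRT18, POU5F1, NANOG and SOX2 were negative under median centring (-0.29, -0.17, -0.22 and -0.11). The smallest p-values were those of ESRRB (0.55 ± 0.14, adjusted p = 0.0567), with 1.17 in heifer 3 and 0.26 to 0.40 in the others, and LIN28A (0.50 ± 0.15, adjusted p = 0.0842).

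Among 18 detected genes of junctions and ion transport, which build the blastocoel, the tight junction adhesion molecule F11R fell (-0.44 ± 0.10) and 17 did not pass. Adjusted over the list alone, 3 were higher (CTNNB1, AQP11 and CLDN7) and 4 lower (F11R, JUP, TJP1 and CLDN6). In this and the following lists, members other than the 2 with the smallest p-values, those that passed over all genes and the fixed markers were named after their values were seen. Of 17 genes of the primitive endoderm and basement membrane 0 passed, and 1 was lower adjusted over the list alone, fibronectin FN1 (-0.60 ± 0.14). COL4A2, a basement membrane collagen, had -0.25 ± 0.10, of uncertain size since it was above background in 1 of 4 samples at 8 months. Of 6 detected trophoblast secretory genes 0 passed, over all genes or adjusted over the list alone; TKDP1 had -0.80 ± 0.24 (adjusted p = 0.0887) and PAG2 -0.23 ± 0.15. Of 18 genes of retinoid and growth factor signalling 0 passed by either adjustment, with -0.30 ± 0.10 for FGFR2 and -0.36 ± 0.12 for BMP4.

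In cholesterol synthesis, MVD (0.72 ± 0.14) and MSMO1 (0.47 ± 0.10) rose at 8 months and TM7SF2 fell (-0.72 ± 0.11), and 18 of 21 genes did not pass. Adjusted over the list alone, 8 were higher and 1 lower. In fatty acid handling and PPAR targets FADS2 rose (0.54 ± 0.12) and 24 of 25 did not pass. Adjusted over the list alone 1 was higher and 1 lower, the acyltransferase AGPAT1. This gene was above background in 0 of 4 samples at 8 months and 3 of 4 at 14 months. Its background bound was 1.39-fold lower at 8 months (adjusted p = 0.0518 over all genes, not passing). Of 49 genes of oxidative phosphorylation, the respiratory chain subunits NDUFB10 (0.46 ± 0.10) and NDUFA4 (0.46 ± 0.10) rose and 47 did not pass, with 8 higher and 3 lower adjusted over the list alone. Citrate synthase, CS, rose (0.68 ± 0.10) among 19 genes of the TCA cycle and pyruvate, with 1 higher and 3 lower (SUCLG2, IDH3G and MDH1) adjusted over the list alone. None of 20 glycolysis genes passed by either adjustment; PFKL had 0.47 ± 0.12 and ENO1 0.34 ± 0.10, with the opposite sign in another probe of ENO1. Of 20 genes of amino acid transport and one-carbon metabolism the transporter SLC7A5 fell (-0.60 ± 0.12), also adjusted over the list alone, and SLC1A1 had 0.52 ± 0.17. Of 27 genes of mTOR and insulin signalling 0 passed by either adjustment; MTOR had -0.18 ± 0.10 and PDPK1 0.35 ± 0.12. The insulin receptor INSR was above background in 0 of 4 samples at 8 months and 3 of 4 at 14 months. Its background bound was 1.23-fold lower at 8 months, and the difference did not pass (adjusted p = 0.0827).

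Cytosolic ribosomal proteins were measured for 61 genes, of which RPS2 (-0.66 ± 0.14) and RPS7 (-0.52 ± 0.11) fell and 59 did not pass, with 2 lower adjusted over the list alone. Another detected probe of RPS7 had the opposite sign. Of 61 mitochondrial ribosomal protein genes MRPL28 rose (0.59 ± 0.12) and 60 did not pass, with 5 higher and 0 lower adjusted over the list alone (MRPL28, MRPS34, MRPL14, MRPL24 and MRPS23). MCM5, a subunit of the replicative helicase, fell (-0.59 ± 0.12) among 37 genes of the cell cycle and DNA replication, with 1 lower adjusted over the list alone, and PCNA had -0.46 ± 0.11 (adjusted p = 0.0566, with the same sign in 2 of 4 detected probes). Of 27 genes of DNA methylation and chromatin, the histone deacetylase HDAC1 (-0.71 ± 0.11) and the demethylase KDM1A (-0.57 ± 0.10) fell, with 3 lower adjusted over the list alone, CBX3 being the other. Of 2 detected probes of KDM1A, 1 had this sign. Of 9 imprinted genes 0 passed by either adjustment; GNAS had -0.53 ± 0.15 and IGF2R 0.25 ± 0.10.

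Among stress responses, HSPA1A (0.70 ± 0.15) and DNAJB1 (0.49 ± 0.10) rose of 15 heat shock genes, 2 also adjusted over the list alone, in heifers 3 and 4 and not on average in heifers 1 and 2. Of 3 detected probes of DNAJB1, 1 had this sign. Of 29 genes of the oxidative stress response 0 passed. Adjusted over the list alone 3 were higher and 3 lower, among them superoxide dismutase SOD1 (0.59 ± 0.15) and the mitochondrial peroxiredoxin PRDX3 (-0.51 ± 0.13). Their regulator NFE2L2 had -0.13 ± 0.11, with 0.485, 0.11, -0.513 and -0.593 in heifers 1 to 4. Of 21 genes of the unfolded protein response 0 passed by either adjustment, with -0.55 ± 0.14 for ATF4 (-1.12 in heifer 2, -0.40 to -0.29 in the others) and 0.53 ± 0.15 for SDF2L1. Of 18 genes of apoptosis and the p53 response 0 passed by either adjustment, with 0.30 ± 0.10 for DIABLO (0.51 in heifer 1, 0.22 to 0.26 in the others) and 0.29 ± 0.13 for FADD. In the interferon response, the class I light chain B2M (0.70 ± 0.10) and IFI35 (0.51 ± 0.10) rose and the signal transducer STAT2 fell (-0.53 ± 0.10) of 9 genes, with 2 higher and 2 lower adjusted over the list alone, where IRF1 (-0.32 ± 0.10) was the other lower one.

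Markers of other possible sources of RNA did not pass by either adjustment. Of 5 detected oocyte genes MOS had 0.20 ± 0.11 and OOEP 0.20 ± 0.10. Of 8 cumulus and granulosa genes HSD3B1 had -0.70 ± 0.23, with 0.56 in heifer 2 and -1.15 to -1.10 in the others, and SERPINE2 had 0.25 ± 0.11. Of 6 sperm genes TNP1 had -0.20 ± 0.13, and PRM1 was above background in 0 of 4 samples at 8 months and 3 of 4 at 14 months. The background bound of PRM1 was 1.13-fold lower at 8 months, with a ratio of 0.02 in heifer 4, and the difference did not pass (adjusted p = 0.108). Of 3 detected blood cell genes, too few for a list test, PTPRC had 0.31 ± 0.12 and CD3E 0.06 ± 0.10. For the sex of the embryos, the only detected Y-linked gene DDX3Y had 0.10 ± 0.10, and of 17 X-linked genes 0 passed, with -0.02 ± 0.10 for XIST, 0.33 ± 0.10 for HDAC8 and -0.48 ± 0.13 for SRPX2. DDX3Y was above background in 3 of 4 samples at 8 months and 2 of 4 at 14 months. XIST was above it in 3 of 4 at each age. Both ratios are therefore of uncertain size and do not settle whether the sex of the embryos differed.

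**Figure D3:**
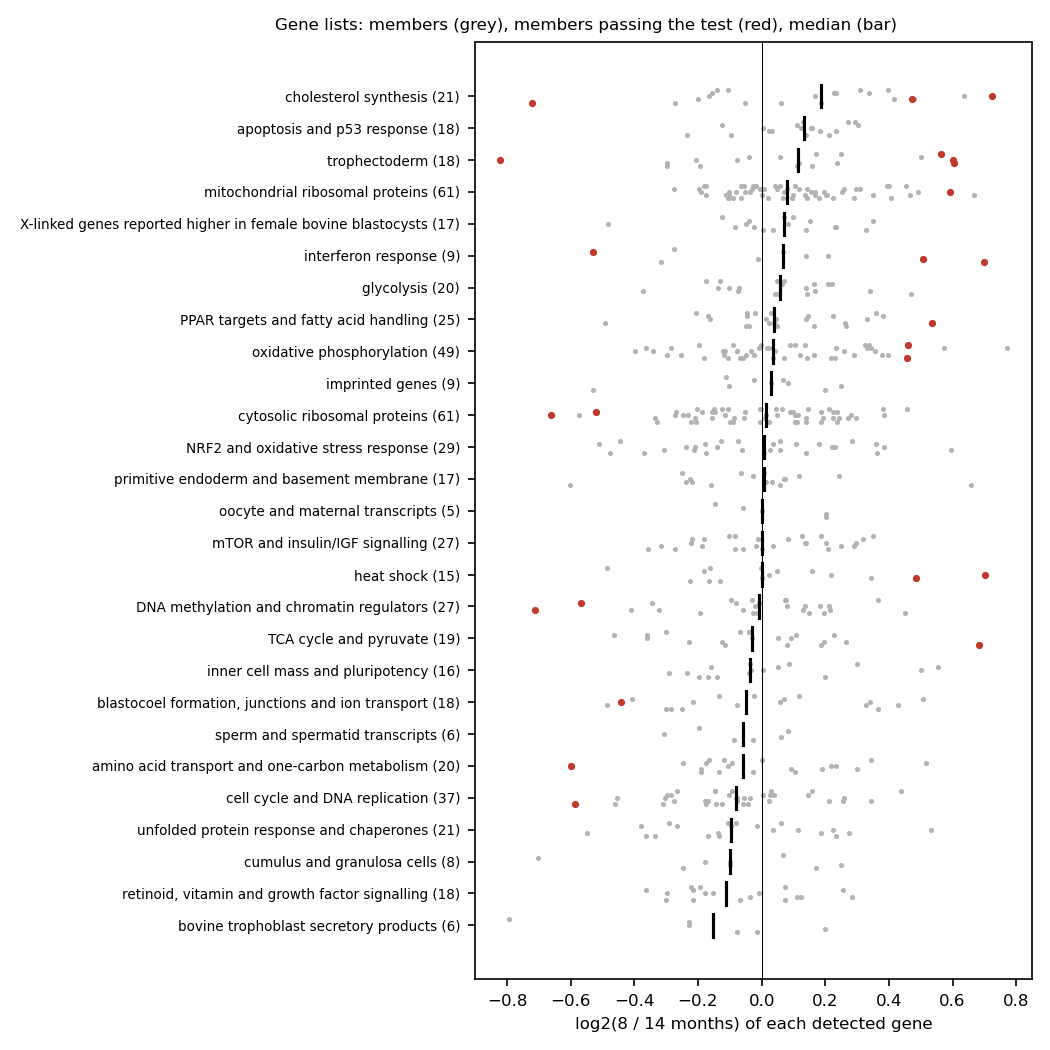
The log2 ratio of 8 over 14 months (x axis) is plotted for each detected gene of the 27 tested lists (y axis, with the number of detected genes), in grey or, where the gene passed, in red, with the list's median as a bar. The medians run from -0.15 (trophoblast secretory products) to 0.19 (cholesterol synthesis), and most lists spread to both sides of 0; under median centring the cholesterol synthesis median was -0.05.

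With the processing described above, no list as a whole passed. Camera called 0 of 27 lists, with 3 at an unadjusted p under 0.05, and fry called 0, with 2 at an unadjusted p under 0.05. The simulated lists were shifted by 0.4, held uncorrelated probes and were judged at an unadjusted p. In the tested lists, the estimated correlation ran from -0.208 (oocyte genes) to 0.589 (trophoblast secretory products). Shifts smaller than 0.4 were not simulated, so the counts of called lists do not exclude them. Nor do these counts exclude larger shifts in lists that are correlated or shorter than the simulated ones. The mitochondrial ribosomal proteins had a median of 0.08, with 39 of 61 genes above 0 (adjusted p = 0.16). Cholesterol synthesis had 0.19, with 13 of 21 above 0, and apoptosis and the p53 response 0.13, with 15 of 18 above 0 (adjusted p = 0.261 for both). These 3 medians were -0.19, -0.05 and -0.07 under median centring. With an estimated correlation the smallest adjusted p of the 27 lists was 0.996. Fry's test for change in either direction, which does not compare a list with other genes, called 15 of 27. The median, the mean or the direction of camera differed in sign for the lists of pluripotency, primitive endoderm, oxidative stress, cytosolic ribosomal proteins, imprinted genes and amino acid transport. Without heifer 1, camera called 2 lists, mitochondrial ribosomal proteins (adjusted p = 0.0108) and cholesterol synthesis (adjusted p = 0.0161), and without heifer 3 both had an adjusted p of 0.023. Under median centring the cytosolic ribosomal proteins were called lower, with a median of -0.39 (adjusted p = 0.000229).

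The third comparison concerned the dye itself. The dye coefficient of HSPA1A, DNAJB1 and FADS2 is the same contrast as a difference of their age ratio between heifers 1 and 2 and heifers 3 and 4, since no heifer was hybridised in both orientations. Over all probes, 18 of 17685 had a dye coefficient that passed (limma, adjusted p under 0.05), 2 higher and 16 lower in Cy5, and 3358 had an unadjusted p under 0.05. The count depends on the processing and ran from 0 without background correction to 352 without the filter on dim probes, and without heifer 1, 2, 3 or 4 it was 0, 0, 110 and 491.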

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

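No test in this part was chosen after the result was seen. Among the 4 heifer ratios of each of 93 named genes, 5 genes had 1 heifer far from the other 3, where chance gives about 4.6, so these values carry no explanation. MPDU1 was at 1.45 in heifer 3 against 0.56 to 0.67 in the others, and ESRRB was at 1.17 in heifer 3 against 0.26 to 0.40. DIABLO was at 0.51 in heifer 1 against 0.22 to 0.26. ATF4 was at -1.12 in heifer 2 against -0.40 to -0.29. HSD3B1 was at 0.56 in heifer 2 and between -1.15 and -1.10 in the other 3.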

How the results depend on the processing

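Mean pixel intensities, negative controls as background and each dye orientation alone were chosen after the data were seen. Where no reason is given, the cause was not tested. The 378 genes that passed, or the 301 of them above background in all 8 samples, kept their sign in every setting with 3 or 4 heifers, except for 1 gene with the mean of a gene's probes. Without the dye term or with other moderation the fitted ratio is the same, so no sign could turn there. The genes were also chosen on these same arrays, which favours a kept sign in the other settings, so this is no independent support. Of the 378, 371 had an unadjusted p under 0.05 without the dye term and 288 without moderation, where fewer degrees of freedom enter the test. The 4422 dimmest probes tested had 0 higher and 32 lower calls, and whether low signal over background is the reason was not tested.

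Against 332 probes, 0 passed with no dye term, no background correction, plain subtraction, no moderation or mean pixel intensities. The smallest adjusted p (limma) was 0.0449 with the main settings, 0.0596 with plain subtraction and 0.0677 with no background correction. For these 2 settings the fall to 0 thus reflects a small move across the threshold. There were 585 with an offset of 16, 3416 with median centring (81 higher, 3335 lower), 1013 with no filter, where more probes were tested, and 1055 with trended and robust moderation. The count at an unadjusted p and 1.5-fold, 486, became 1411 with median centring (22 higher, 1389 lower), 237 with no moderation and 170 with mean pixel intensities. Against 378 genes there were 0 with no dye term, no moderation or mean pixel intensities, 2078 with median centring (39 higher, 2039 lower), 701 with trended and robust moderation and 207 with the mean of a gene's probes, of which 266, 360 and 203 were among the 378. Of the 494 genes from the authors' ratios, 375 were.

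Probes with a dye effect, 18, became 0 with no background correction, plain subtraction, trended and robust moderation, no moderation, mean pixel intensities or negative controls as background. They became 46 with an offset of 16, 295 with median centring, 352 with no filter, 50 where all 8 samples had to be above background, and 40 with either the authors' normalized table or the series values. List calls went from 0 to 1 with median centring, where the cytosolic ribosomal proteins turned to a median of -0.39, and to 1 with mean pixel intensities (mitochondrial ribosomal proteins, adjusted p = 0.0266).

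Leaving out 1 heifer at a time, where the lone array of an orientation is assumed to vary like the others, gave 0 to 1180 probes (0 without heifer 1 or 2, 358 without heifer 3 and 1180 without heifer 4), 435 to 821 probes at an unadjusted p and 1.5-fold, 0 to 339 genes, 0 to 491 probes with a dye effect and 0 to 2 lists. Without heifer 4, 173 of the 378 genes passed. Within 1 dye orientation, 3 named genes that passed turned sign: HSPA1A (-0.31) and DNAJB1 (-0.049) in heifers 1 and 2, and FADS2 (-0.086) in heifers 3 and 4. Aquantile scaling leaves the ratios as they are, so it tests nothing but the choice of probe per gene. Of the named genes that did not pass, SERPINE2, POU5F1, KRT18, NANOG, SOX2 and XIST turned sign under median centring, SOX2 without heifer 1, NANOG without heifer 2 or 3, and XIST and GATA3 without heifer 4. The medians of 15 of 27 lists turned sign under median centring.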

Other observations

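The families of genes and the tests of explanations in this part were chosen after the results were seen. The 6 detected histocompatibility genes all had positive ratios, also under each scaling, background setting and left-out heifer tried. Their median was 0.17, with 0.09 under median centring, 0.10 without heifer 3 and 0.26 without heifer 4. BoLA-DRB3 (0.78 ± 0.12 SE) and B2M (0.70 ± 0.10) passed over all genes, and JSP.1 (0.17 ± 0.10), BOLA-DMB (0.17 ± 0.12), BOLA-N (0.17 ± 0.10) and BOLA-NC1 (0.08 ± 0.10) did not. Camera gave the family an adjusted p of 0.0418 over 26 families, and an adjusted p of 0.926 with an estimated correlation. The family was drawn up after its leading genes were known, so this is not independent evidence.

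Of 43 detected RNA helicases of the DEAD and DEAH boxes, DHX9 (-0.61 ± 0.10) and DHX8 (-0.49 ± 0.11) were lower at 8 months. At an unadjusted p under 0.05 there were 15 lower and 1 higher, DDX3X (0.27 ± 0.11). The median was -0.12 and was below 0 in each setting tried, but camera gave an adjusted p of 0.116, and 0.926 with an estimated correlation. Of 105 proteins named TMEM, 6 were higher and 1 lower (camera adjusted p = 0.215), and this balance turned under median centring, where the median went from 0.08 to -0.10.

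Probes passed with the dye term (332) and 0 did without it. The 7 ways of turning the 4 arrays that can be fitted beside a dye term are too few for a share under 0.05. The real one gave 332 and the highest of the others 1. Every other turning groups arrays of opposite orientation, so anything shared within an orientation widens its error. The real turning would thus lead with or without an age effect, and the comparison cannot decide. A constant dye bias of each probe may widen the error of a fit that leaves it out: as Cy5 over Cy3, probes above background in no channel deviated together on every pair of arrays (lowest r = 0.24), but tested probes did not across orientations (r = -0.12 to -0.0015), and such a bias cannot be told apart from a difference between the pairs of heifers, as no heifer was hybridised both ways. A component shared by the heifers of one orientation, with no age effect common to all 4, would give the age and dye coefficients equal chances. For age 332 probes passed and for dye 18 (4682 and 3358 at an unadjusted p under 0.05, limma). Both counts were 0 with no background correction, plain subtraction or mean pixel intensities. With so few pairs of heifers, their balance rests on how the pairs happen to correlate, and probes are not independent. The mean correlation across orientations in the age direction was 0.078 ± 0.053 (SD of 4 values). The counts therefore cannot decide, and such a component stays open. The age of the donor, as the biological explanation, stays open with them and cannot be told apart from the order of the collections.

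Probes lower at 8 months outnumbered those higher (234 and 98), but not among genes at an unadjusted p under 0.05 and 1.5-fold (91 and 96). The choice of normalization or background correction moved the share of lower calls from 70.5% to between 64% (the authors' ratios) and 97.6% (median centring) where at least 20 probes passed, so the size of the excess depends on it, and it is argued against only as its whole cause. Dim probes are argued against as the whole cause too, with 63.6% lower among calls in the brighter of 2 equal groups of probes, although the dimmer group had 90.6%. The array of heifer 4, which had the widest negative controls in Cy5 (SD 37.6), is a candidate source: without it 46.5% of 1180 calls were lower, and at an unadjusted p under 0.05 the share went from 58.7% to 52.1% (64.1%, 61.1% and 63.6% without heifer 1, 2 or 3), but the authors' ratios with heifer 4 gave 52.3%. Part of the excess from normalization, and an effect of donor age, stay open.

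In the trophectoderm list, GATA2, TFEB and TEAD4 were higher and DAB2 lower at 8 months. A different share of trophectoderm cells in the pools would move its genes together, and 61.1% of the 18 detected genes lay on the more frequent side, with genes passing on both sides. Where a gene lies depends on the normalization: under median centring the median went from 0.11 to -0.24, 66.7% lay on the lower side, and 0 genes passed as higher and 3 as lower. A change in share therefore stays open, and regulation within the lineage with donor age was not tested.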
